A study of Nicotiana plumbaginifolia and Nicotiana benthamiana and Nicotiana rustica with 81 samples.

How the data were processed

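Hand-dissected floral nectaries of 6 Nicotiana species at 4 stages, and leaf, ovary and sepal of N. plumbaginifolia, were sequenced as RNA in 81 libraries, 3 per group. Whether the 3 libraries of a group come from separate plants is not stated, so they may be technical replicates. The labels list sepal as a tissue, while the protocol text names stems and fewer libraries than the samples listed; the groups here follow the sample titles. The post secretory stage is called post-fertilization in the protocol.

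The deposited table was made by the authors and holds 38230 reference transcripts of N. tabacum, each with a description and, for 33170, an Arabidopsis match, over 12541 loci (2.64 transcripts per locus). Its group means and SDs are in the unit score, which the deposited column names and processing notes describe as normalized counts, written as whole numbers. Its 51 columns of yes or no calls, of unit other, are the authors' deposited differential expression calls, of which 45 are distinct, and their threshold is not given in the sources used here. The submitters' processing notes name DESeq for normalization, and aligner settings and versions are not given in the sources used here. Every transcript reaches 100 or more in some group. The highest SD over mean is 1.733, at the limit of 1.732 that an SD of 3 libraries with n - 1 allows, up to rounding to whole numbers. Totals and values per library are not given in the table, so the depth and the counting precision of each value are unknown.

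The N. clevelandii columns equal the N. bonariensis columns in all 38230 transcripts, means, SDs and calls alike, while the means of other pairs of groups are equal in at most 3.38% of the transcripts above 0 in either group. Which species the values belong to cannot be read from the table. The values were therefore counted once, as the profile deposited under both N. bonariensis and N. clevelandii (the joint profile), so the planned comparison of 6 species became one of 5 profiles with 20 nectary means. Counting both copies was run as an alternative, although it enters identical values as separate profiles.

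The stage effect shared by the profiles was fitted with limma 3.58.1 (R 4.3.3, with the data.table package at version 1.17.8) on log2 of the authors' mean plus 1, with profile as a block, moderated variances with a trend, and Benjamini-Hochberg adjusted p under 0.05. It used the 36627 transcripts with a mean of at least 10 over the 20 nectary means, and left 12 residual degrees of freedom. The profiles are the replicates (n = 5), and the authors' SDs do not enter this test. An exact two-sided sign-flip test over 5 profiles has 32 sign patterns and a smallest p of 0.0625, so it can place nothing past 0.05, and transcripts moving one way in all profiles are counted instead. By chance alone a share of 0.0625 of the transcripts free to move either way would be counted. Such a count is therefore no count of shared changes. Within a profile, between tissues and between species, 2-fold changes of mean plus 1 are counted with no test, as planned for a table without values per library, and the authors' calls are given beside them. The means and SDs of 3 libraries would allow an approximate test from summary values, which was not made. Nectary-enriched means that the lowest of the 4 nectary stages is at least 4-fold above the highest of leaf, ovary and sepal. The tissue comparison was also made on sums over the transcripts of each Arabidopsis locus.

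The 16 gene lists cover sucrose synthesis and export, starch synthesis, starch breakdown, nectary and floral regulators, nectarins and nectar defence, jasmonate, photosynthesis, cell division, carotenoid and ascorbate synthesis, senescence, and nicotine and alkaloid synthesis. Lists of markers of other tissues cover pollen, ovule, style, vascular tissue and trichomes. They, the tests, the naming rule and most alternatives were written before the data were examined. Members were matched by Arabidopsis locus, or else by description. In use, the trichome list holds mostly TRICHOME BIREFRINGENCE-LIKE wall genes, the pollen list proteins named for pollen that other tissues also express, the style list pistil-specific extensins alone, the histones of the cell division list include H3.3, and the RNase pattern of the nectarin list caught exoribonucleases. Lists were tested with limma's camera at a correlation of 0.01 between genes and at an estimated correlation, adjusted over the 16 lists. For the tissues, list medians were set against 10000 random lists of the same size matched on level. Members are also counted with p adjusted over the list alone.

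Transcripts are named by a rule: the 5 largest rises and 5 largest falls past the threshold that moved one way in all profiles and carry a description, the 2 members of each list with the largest absolute change, and 1 nectary gene of each of several textbook functions by its most abundant transcript. The text says where others were chosen after their values were seen. Means are given with the authors' deposited SD of 3 libraries.

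The test was tried on simulated data made from the table with 200 transcripts changed: 25% of the 2-fold and 59% of the 4-fold changes were recovered, 0 with the wrong sign, and 3 of 87 calls were false. The simulated noise was independent between transcripts and of equal spread in all groups. Real transcripts can move together, and 3 nectary groups vary more than the rest. The share of false calls therefore does not carry over to the real counts. Alternatives planned were other pseudocounts (0.1 and 10), other minimums, rescaling by median of ratios, no variance trend, a 2-fold threshold, leaving out each profile, and other ways of matching list members. Added after seeing the data were both copies of the joint profile, sums per locus, and leaving out the 3 groups of widest spread, the groups with raised ovule markers, or leaf. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.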

Results

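RNA of floral nectaries, the glands that secrete nectar, was sequenced from 6 Nicotiana species at 4 stages of flower development. Stage 6 is immature, stage 9 precedes secretion, stage 12 is the open flower at anthesis, and the post secretory stage follows. Leaf, ovary and sepal of N. plumbaginifolia add 3 groups, which makes 27 groups of 3 libraries and 81 libraries in all. The deposited table gives the authors' mean and SD of normalized counts per group for 38230 reference transcripts of N. tabacum, most of them with an Arabidopsis match. The columns of N. clevelandii equal those of N. bonariensis in all 38230 transcripts, so they count once here, as the joint profile, which leaves 5 profiles and 20 nectary means. No totals per library are given and the depth is unknown. The column sums of 7824385 to 15248393 are sums of normalized means. All log2 changes are on the scale of the authors' mean plus 1, and those given with an SE are limma estimates over the 5 profiles.

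From stage 6 to stage 12 the immature nectary becomes the gland of an open flower, and the comparison asks which transcripts moved one way across the genus. Phytoene synthase 2-like (XM_016615435.1), the entry enzyme of carotenoid synthesis, rose by 3.61 (SE 0.65, adjusted p = 0.026, higher in 5 of 5 profiles), from an authors' mean of 68 (SD 10) to 5081 (SD 234) in N. rustica. A beta-amylase 3-like transcript (XM_016591116.1), of the enzyme family that releases maltose from starch, rose by 3.12 (SE 0.62, adjusted p = 0.037, 5 of 5). A pair of NAC transcription factor 29-like transcripts, whose Arabidopsis relative promotes senescence, rose by 3.81 (XM_016636746.1, SE 0.6, adjusted p = 0.015, 5 of 5) and 3.33 (XM_016602248.1, SE 0.66, adjusted p = 0.036, 5 of 5). The largest fall among transcripts lower in all profiles was that of a response regulator-like APRR1 transcript (XM_016653577.1), a relative of a part of the circadian clock, with -6.76 (SE 0.87, adjusted p = 0.0061, lower in 5 of 5). Its authors' mean went from 5127 to 197 in N. rustica and from 293 to 1 in N. benthamiana.

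The largest rises past the threshold and in all 5 profiles included a lipid-transfer protein 3-like transcript (XM_016600359.1, 6.74, SE 1.11, adjusted p = 0.02), whose family binds lipids outside the cell. It was listed at 0 in stage 6 of N. plumbaginifolia and of the joint profile and had authors' means of 1720 and 792 there at stage 12. A TAS14-like dehydrin (XM_016652582.1), of a family induced by abscisic acid and drought, rose by 5.38 (SE 0.67, adjusted p = 0.0059). Chalcone synthase 2 (XM_016634418.1), the entry enzyme of flavonoid synthesis, rose by 5.04 (SE 0.98, adjusted p = 0.035). The wall-remodelling xyloglucan endotransglucosylase/hydrolase 23 (XM_016608389.1) rose by 5.02 (SE 0.91, adjusted p = 0.026) and a mavicyanin-like copper protein (XM_016634767.1) by 4.98 (SE 1.06, adjusted p = 0.044). In N. plumbaginifolia the lipid-transfer transcript had a mean of 3525 in ovary and 0 in leaf and sepal. The mavicyanin-like one had 2834 in ovary, 0 in leaf and 2 in sepal. In the same order, chalcone synthase 2 had 1295, 695 and 645, the hydrolase 245, 230 and 106, and the dehydrin 1176, 11716 and 5922. Whether ovary RNA adds to these rises was not tested. Falls in 5 of 5 profiles were those of the petal growth regulator relative BPE-like (XM_016625665.1, -3.48, SE 0.44, adjusted p = 0.0059), of bHLH113 (XM_016636616.1, -3.26, SE 0.66, adjusted p = 0.037) and of a YABBY 4-like transcript (XM_016621945.1, -2.96, SE 0.27, adjusted p = 0.0008), a member of a family that patterns floral organs. A chloroplast chaperonin, the RuBisCO large subunit-binding protein alpha-like (XM_016647565.1), fell as well (-2.96, SE 0.44, adjusted p = 0.013).

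**Figure D1:**
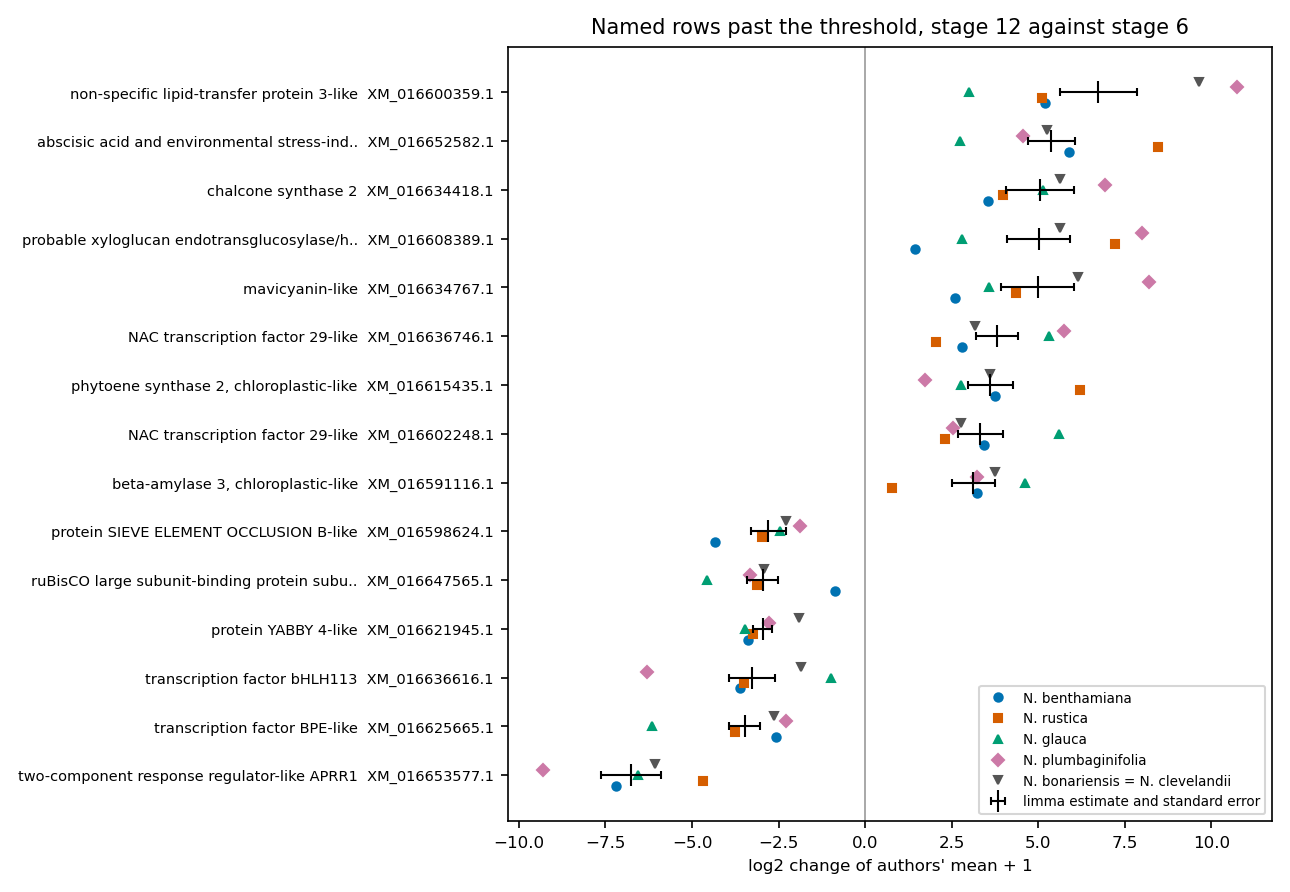
Log2 change of the authors' mean plus 1 from stage 6 to stage 12 (x axis) for the 15 named transcripts past the threshold, with 1 marker per profile and the limma estimate with its standard error in black. The estimates run from -6.76 for the APRR1-like transcript to 6.74 for the lipid-transfer protein 3-like transcript, and all 5 profiles lie on 1 side of 0 for each.

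The nectar sugar, nectarin and regulator transcripts named next did not pass the test in this step, unlike the beta-amylase 3-like transcript above. The NEC1-like sugar transporter of the Arabidopsis locus SWEET9 (XM_016615427.1), which exports sucrose from nectary cells, had an estimate of 3.80 (SE 1.32, adjusted p = 0.17) and was higher in 5 of 5 profiles. Its authors' means went from 12265 (SD 296) to 70716 (SD 2105) in N. benthamiana, from 249 (SD 2) to 3145 (SD 150) in N. rustica and from 2152 (SD 69) to 28771 (SD 12673) in N. glauca. They went from 154 (SD 15) to 7619 (SD 232) in N. plumbaginifolia and from 514 (SD 20) to 5742 (SD 951) in the joint profile. Cell wall invertase 4-like (XM_016593154.1), which splits sucrose outside the cell, had 0.58 (adjusted p = 0.73, higher in 4 of 5 profiles). Nectarin-1 (XM_016580669.1), a germin-like nectar protein, had 0.83 (adjusted p = 0.5, higher in 3), nectarin-3-like (XM_016588226.1) 0.72 (adjusted p = 0.67, higher in 2) and the transcript listed as nectarin 4, KJ874398.1, 1.44 (adjusted p = 0.3, higher in 4). Its description gives only an endoglucanase inhibitor, and the name nectarin 4, used below, is that of the list. The nectary regulators CRABS CLAW-like (XM_016610040.1) and myb-related protein 305-like (XM_016582512.1) had -0.08 (adjusted p = 0.97) and -0.10 (adjusted p = 0.97), each higher in 2 and lower in 3 profiles. Beta-amylase 1-like (XM_016660106.1) had 0.99 (adjusted p = 0.3, 5 of 5 higher), the ADP-glucose pyrophosphorylase XM_016653552.1 of starch synthesis 0.62 (adjusted p = 0.5) and the sucrose-phosphate synthase XM_016579794.1 0.35 (adjusted p = 0.58).

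Among the 126 cell division transcripts (cyclins, replication factors and core histones) the list as a whole fell from stage 6 to stage 12, with a median of -0.40. Its camera test had an adjusted p = 7.2e-08, against an adjusted p = 0.65 with an estimated correlation, and 0 members passed alone, over all genes or adjusted over the list alone. Medians per profile cover only the members measured in it, a different set in each. They were -0.76 in N. benthamiana (n = 83), -1.06 in N. rustica (n = 78), -2.20 in N. glauca (n = 70), -0.77 in N. plumbaginifolia (n = 70) and 0.25 in the joint profile (n = 106). Of 45 carotenoid and ascorbate synthesis members, 1 rose and 0 fell over all genes (4 rose and 2 fell adjusted over the list alone). Beta-carotene hydroxylase 2-like (XM_016611556.1) had an estimate of 4.72 (adjusted p = 0.064) and was higher in 4 profiles and lower in 1. Of 59 starch breakdown members, 1 rose and 1 fell (1 and 2 adjusted over the list alone); the 1 that fell, glycogen phosphorylase 1-like XM_016604217.1 at -1.07 (SE 0.21, adjusted p = 0.036), is named because of its value. Of 26 senescence members 2 rose, also adjusted over the list alone, and of 23 vascular markers 1 fell (3 adjusted over the list alone), a SIEVE ELEMENT OCCLUSION B-like transcript of the phloem (XM_016598624.1, -2.80, SE 0.5, adjusted p = 0.025).

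In the other 11 lists 0 members passed limma's test from stage 6 to stage 12 over all genes. Adjusted over the list alone, 1 of 30 sucrose synthesis and export members rose, 1 of 54 nectarin and defence members fell, and of 48 jasmonate members 2 rose and 1 fell. None passed either way among 123 photosynthesis, 49 starch synthesis, 48 nectary and floral regulator, 9 nicotine and alkaloid, 39 pollen-named, 14 ovule and 3 style transcripts and 65 transcripts named for trichomes. No list but cell division was past camera's threshold, with adjusted p from 0.11 to 0.65. Camera's direction differed in sign from the median for jasmonate (median 0.01) and for the regulators (median 0.02), and the trichome list had a median of -0.01 beside a mean of 0.05. The ovule markers, of a tissue next to the nectary, had medians of -0.13 in N. benthamiana (n = 9), 1.15 in N. rustica (n = 9), 0.74 in N. glauca (n = 3), 0.64 in N. plumbaginifolia (n = 7) and 1.96 in the joint profile (n = 10).

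Over all 36627 transcripts tested, limma placed 175 higher and 132 lower at stage 12 than at stage 6, 307 in all, and 6136 had an unadjusted p under 0.05. The share of the 307 that rose was 57%, and after rescaling the means by median of ratios it was 47.1%, of 291. The count was 105 without N. benthamiana, 4 without N. rustica, 41 without N. glauca, 114 without N. plumbaginifolia and 27 without the joint profile, with 8, 1, 5, 7 and 4 of the 15 named transcripts still past the threshold. It was 0 (4967 unadjusted, 0 of the 15 named) without the 7 groups in which ovule markers stood 5-fold or more above stage 6 of the same profile, and 72 without the 3 groups of widest spread between libraries.

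Between stages 6 and 9, before secretion starts, no single transcript passed, and the values of the named ones follow. The ovule identity genes, AGL11 homologs, had the highest estimates among the ovule markers: 3.26 for XM_016616449.1 (SE 0.83, adjusted p = 0.37) and 2.44 for XM_016619520.1 (SE 0.72, adjusted p = 0.42), each higher in 5 of 5 profiles. The former had authors' means of 17 and 715 at stages 6 and 9 in N. plumbaginifolia, 44 and 511 in N. benthamiana and 35 and 1140 in the joint profile. SWEET9 had 2.91 (SE 1.32, adjusted p = 0.61), the beta-amylase 3-like transcript 2.15 (SE 0.62, adjusted p = 0.42), phytoene synthase 2-like 1.80 (SE 0.65, adjusted p = 0.54) and NAC29-like XM_016636746.1 2.16 (SE 0.6, adjusted p = 0.39), all higher in 5 of 5. An auxin response factor 8-like transcript (XM_016637924.1), of a family that acts in flower maturation, had -1.08 (SE 0.3, adjusted p = 0.4) and a jasmonate repressor (KC246551.1) -1.10 (SE 0.3, adjusted p = 0.39), both lower in 5 of 5.

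As lists, the 14 ovule markers rose from stage 6 to stage 9 (median 0.54, camera adjusted p = 0.013, against an adjusted p = 0.68 with an estimated correlation), with 0 members past over all genes and 3 adjusted over the list alone. The 49 starch synthesis members fell (median -0.18, adjusted p = 0.027, and adjusted p = 0.8 with an estimated correlation), and so did the 126 cell division members (median -0.20, adjusted p = 0.039, and adjusted p = 0.84 with an estimated correlation), each with 0 members past in either count. Over the measured members, again 9, 9, 3, 7 and 10, the ovule medians were 1.25 in N. benthamiana, 0.51 in N. rustica, 0.81 in N. glauca, 3.19 in N. plumbaginifolia and 2.47 in the joint profile, and these are the markers of another tissue that move with the step. The cell division median was 0.09 without N. rustica, with camera's direction turned, and that call was also lost without N. glauca. The ovule call was lost without N. plumbaginifolia and without the joint profile, and the starch synthesis call without either of these or N. glauca. Over all transcripts limma placed 0 past the threshold and 2990 at an unadjusted p under 0.05, and 2166 moved one way in all 5 profiles, for which the exact two-sided sign-flip p of 0.0625 is the smallest it can give. By chance alone a share of 0.0625 would move so, and 2166 is no count of shared changes. Without N. glauca limma placed 3 past the threshold.

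Between stages 9 and 12, as secretion begins, the plastid glucose 6-phosphate translocator GPT2-like (XM_016596315.1), which feeds starch synthesis, had an estimate of 2.40 (SE 0.69, adjusted p = 0.98) and was higher in 5 of 5 profiles. Nectarin 4 had 1.85 (SE 0.68, KJ874398.1), phytoene synthase 2-like 1.81 (SE 0.65), beta-amylase 1-like 1.03 (SE 0.46) and a plastid glucan phosphorylase (XM_016590767.1) 1.03 (SE 0.41), all higher in 5 of 5 with an adjusted p = 0.98. The ADP-glucose pyrophosphorylase XM_016653552.1 had 1.33 (SE 0.45, adjusted p = 0.98, higher in 4 and lower in 0). SWEET9 had 0.89 (SE 1.32, adjusted p = 0.98), higher in 3 and lower in 2, with 5862 and 3145 as authors' means at stages 9 and 12 in N. rustica and 1233 and 7619 in N. plumbaginifolia. The SIEVE ELEMENT OCCLUSION B-like transcript had -1.61 (SE 0.5, adjusted p = 0.98, lower in 5 of 5).

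Camera placed 3 lists past the threshold in this step, all of them at an adjusted p = 0.5 with an estimated correlation. The cell division list fell (median -0.21, adjusted p = 1.4e-06, n = 126), the starch synthesis list rose (median 0.22, adjusted p = 0.00033, n = 49) and the vascular list fell (median -0.15, adjusted p = 0.0086, n = 23), each with 0 members past over all genes or adjusted over the list alone. Over the measured members (n = 83, 78, 70, 70 and 106), the cell division medians were -1.19 in N. benthamiana, 1.63 in N. rustica, -1.41 in N. glauca, -1.31 in N. plumbaginifolia and 0.12 in the joint profile. The ovule list had a median of -0.52 (adjusted p = 0.064). The starch synthesis call was lost without N. benthamiana and the vascular call without the joint profile. Over all transcripts limma placed 0 past the threshold, 1776 had an unadjusted p under 0.05, and 1431 moved one way in all 5 profiles (exact sign-flip p of 0.0625). Chance alone would again move a share of 0.0625 so.

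After secretion, from stage 12 to the post secretory stage, the sugar exporter, the invertase, nectarin-1 and 3 regulators fell in all 5 profiles. The endoglucanase inhibitor listed as nectarin 4 (KJ874398.1) had 0.60 (adjusted p = 0.68, higher in 3 and lower in 2). SWEET9 (XM_016615427.1) fell by 7.01 (SE 1.32, adjusted p = 0.027), from an authors' mean of 28771 (SD 12673) to 11 (SD 4) in N. glauca and from 7619 (SD 232) to 2595 (SD 76) in N. plumbaginifolia. Cell wall invertase 4-like (XM_016593154.1) fell by 5.29 (SE 0.8, adjusted p = 0.0074) and nectarin-1 (XM_016580669.1) changed by -4.33 (SE 0.61, adjusted p = 0.005). A pair of myb-related protein 305-like transcripts, relatives of a regulator of nectarin genes, fell by 6.80 (XM_016644811.1, SE 0.97, adjusted p = 0.0056) and 6.65 (XM_016582512.1, SE 1.06, adjusted p = 0.01), and CRABS CLAW-like (XM_016610040.1), needed for nectaries to form in Arabidopsis, changed by -5.07 (SE 0.7, adjusted p = 0.005). Photosynthesis transcripts rose as a group, among them oxygen-evolving enhancer protein 3-2 of photosystem II (XM_016587038.1, 3.66, SE 0.59, adjusted p = 0.01, 5 of 5 profiles).

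**Figure D2:**
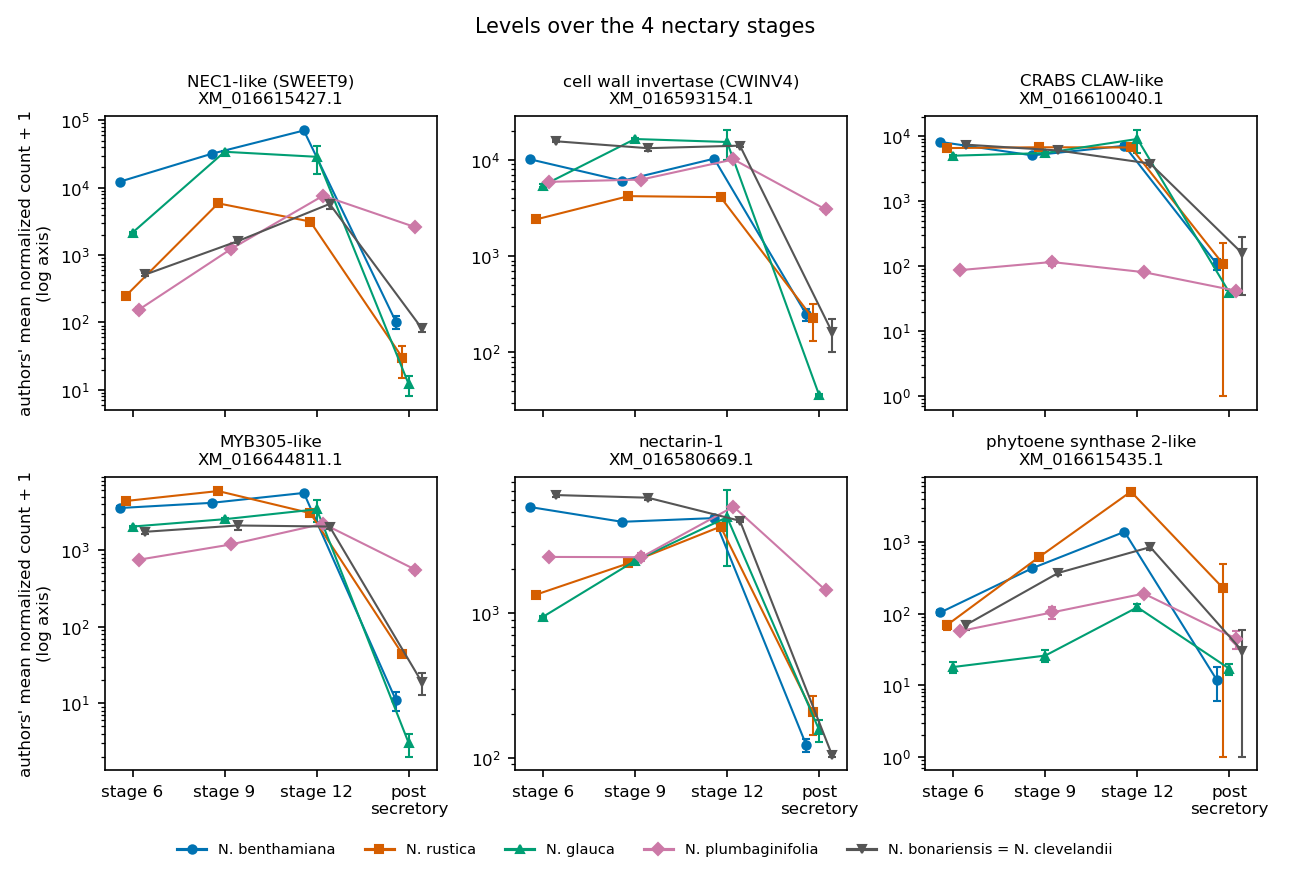
Authors' mean normalized count plus 1 (y axis, log scale) over the 4 nectary stages (x axis) for 6 named transcripts, with 1 line per profile and the authors' SD of 3 libraries as bars, drawn down to 1 where the SD reaches the mean. From stage 12 to the post secretory stage all 6 transcripts fell in all 5 profiles, and the NEC1-like (SWEET9) mean in N. plumbaginifolia went only to 2595.

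The other largest falls in all 5 profiles were those of a cannabidiolic acid synthase-like transcript (XM_016601690.1, -7.25, SE 1.13, adjusted p = 0.0082), whose Arabidopsis match is a berberine bridge-type oxidase, and of a secoisolariciresinol dehydrogenase-like transcript (XM_016584549.1, -5.86, SE 0.72, adjusted p = 0.0029). The former went from 98324 (SD 5185) to 239 (SD 130) in N. rustica. Largest among the rises was a GAST1-like transcript (XM_016589707.1, 4.97, SE 0.62, adjusted p = 0.0029), of a gibberellin-responsive family of small secreted proteins, which went from 35 (SD 9) to 2769 (SD 177) in N. benthamiana. An uncharacterized transcript with photosystem II subunit X as its Arabidopsis match (XM_016599375.1) rose by 3.74 (SE 0.51, adjusted p = 0.0049). UDP-glucuronate 4-epimerase 6-like (XM_016653661.1), of pectin precursor synthesis, rose by 3.71 (SE 0.56, adjusted p = 0.0073) and an isoflavone reductase homolog (XM_016630531.1) by 3.54 (SE 0.45, adjusted p = 0.0029). Each rose in 5 of 5 profiles.

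**Figure D3:**
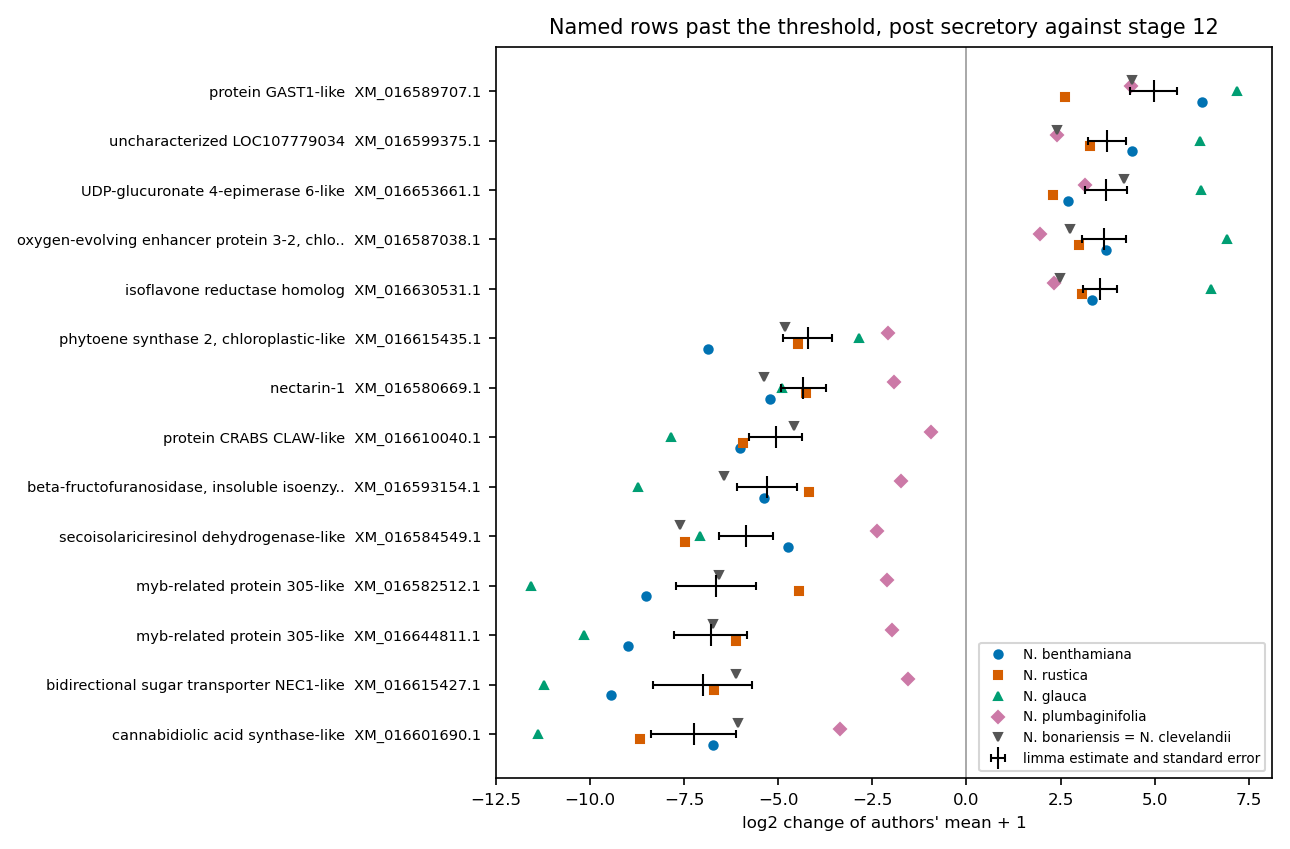
Log2 change of the authors' mean plus 1 from stage 12 to the post secretory stage (x axis) for the 14 named transcripts past the threshold, with 1 marker per profile and the limma estimate with its standard error in black. Falls reach -7.25 and rises 4.97, and among the 9 that fell N. plumbaginifolia has the smallest fall of the 5 profiles.

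Of 123 photosynthesis transcripts 8 rose and 0 fell from stage 12 to post secretory over all genes, and 35 rose and 1 fell adjusted over the list alone (median 1.35, camera adjusted p = 3e-29, and adjusted p = 0.013 with an estimated correlation). Over the members measured in each profile, fewer than the 123, the medians were 2.39 in N. benthamiana (n = 72), 2.69 in N. rustica (n = 71), 5.87 in N. glauca (n = 47), 1.41 in N. plumbaginifolia (n = 64) and 2.31 in the joint profile (n = 92). Further members that rose, named here after their values were seen, are chlorophyll a-b binding protein 50 (XM_016600904.1, 3.52), photosystem I subunit XI (XM_016588736.1, 3.34) and CP26 (XM_016644018.1, 2.04). The 23 vascular markers rose as a list (median 1.05, adjusted p = 6.7e-11, and adjusted p = 0.013 with an estimated correlation), with 0 members past over all genes and 10 higher adjusted over the list alone. Secondary wall cellulose synthases had the highest estimates among them, 3.29 for CesA4-like XM_016612517.1 (SE 0.78, adjusted p = 0.068, higher in 4 and lower in 0) and 2.59 for CesA7 XM_016630818.1 (SE 0.72, adjusted p = 0.11). Over the measured members the vascular medians were 2.71 in N. benthamiana (n = 12), 2.37 in N. rustica (n = 13), 4.06 in N. glauca (n = 11), 0.10 in N. plumbaginifolia (n = 9) and 1.49 in the joint profile (n = 15), a marker list of another tissue that moves with the photosynthesis list.

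Of 45 carotenoid and ascorbate synthesis members 10 fell and 0 rose over all genes, and 14 fell and 4 rose adjusted over the list alone (median -0.41, adjusted p = 1e-04, and adjusted p = 0.017 with an estimated correlation). Phytoene synthase 2-like (XM_016615435.1) fell by 4.22 (SE 0.65, adjusted p = 0.0078, 5 of 5), and among members named after their values were seen phytoene desaturase (XM_016642615.1) fell by 3.40, zeta-carotene desaturase (JF975566.1) by 3.12 and lycopene beta cyclase (XM_016633695.1) by 1.45, all enzymes of the carotenoid pathway. Of 30 sucrose synthesis and export members 6 fell and 0 rose (8 fell and 3 rose adjusted over the list alone), with an adjusted p = 0.0053 for the list and an adjusted p = 0.3 with an estimated correlation. Beside SWEET9 and the invertase, a second NEC1-like transcript (XM_016577514.1, -5.13), sucrose-phosphate synthase 2 (XM_016607051.1, -2.30), sucrose-phosphatase 2 (XM_016645471.1, -1.60) and a sucrose synthase-like transcript (XM_016604254.1, -2.24) make up the 6, named after their values were seen. Of 48 nectary and floral regulators 4 fell (8 adjusted over the list alone), the floral organ gene AGAMOUS-like (XM_016580095.1, -2.10, chosen after its value was seen) beside CRABS CLAW-like and the myb-related pair; the list's camera adjusted p was 0.34.

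Of 65 transcripts named for trichomes, nearly all of them TRICHOME BIREFRINGENCE-LIKE wall acetylation genes, 1 rose (2 adjusted over the list alone; median 0.35, adjusted p = 2.1e-06, and adjusted p = 0.026 with an estimated correlation). Of 39 pollen-named transcripts 0 passed, 5 were higher and 2 lower adjusted over the list alone, and the list rose (median 0.26, adjusted p = 0.02, and adjusted p = 0.43 with an estimated correlation). Among 54 nectarin and defence members 1 rose and 1 fell (1 and 2 adjusted over the list alone), nectarin-1-like XM_016657282.1 at 1.22, named after its value was seen, against nectarin-1. Of 26 senescence members 1 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.05 for the list when rounded, which did not pass). In the jasmonate, starch synthesis, starch breakdown, cell division, nicotine, ovule and style lists 0 passed limma's test over all genes (1 nicotine member fell adjusted over the list alone), and camera's adjusted p lay between 0.23 and 0.96. The sign of camera's direction was opposite to that of the mean for starch breakdown (mean -0.04). Pollen-named transcripts lost their call without N. glauca, as did the sucrose list, and the ovule medians ran from -2.07 over 10 transcripts in the joint profile to 2.76 over only 3 in N. glauca.

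**Figure D4:**
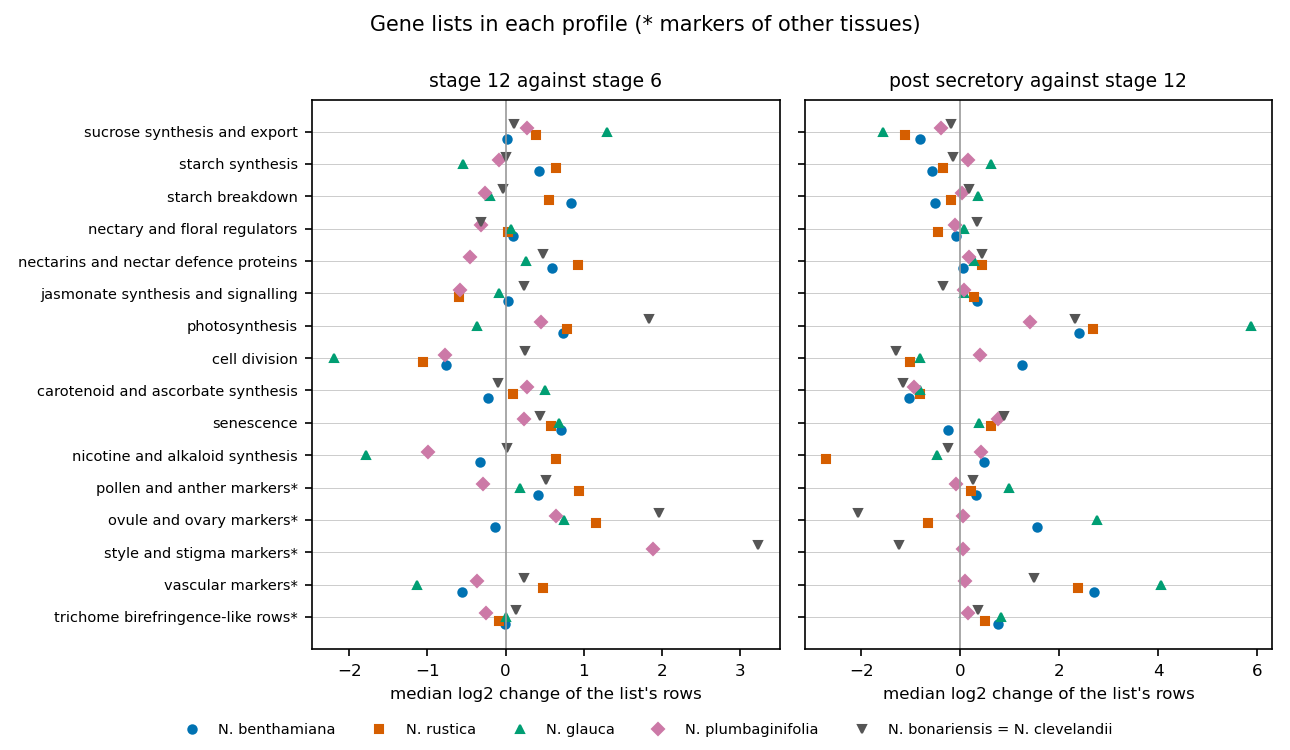
Median log2 change of each gene list's transcripts measured in a profile (x axis), from stage 6 to stage 12 on the left and from stage 12 to post secretory on the right, with 1 marker per profile. From stage 12 to post secretory the photosynthesis medians lie between 1.41 and 5.87 and the carotenoid and ascorbate medians between -1.15 and -0.81.

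Over all transcripts limma placed 85 higher and 203 lower at the post secretory stage than at stage 12, 288 in all, and 5955 had an unadjusted p under 0.05. The count was 35 without N. benthamiana, 33 without N. rustica, 35 without N. glauca, 724 without N. plumbaginifolia and 2 without the joint profile, with 4, 4, 4, 14 and 0 of the 14 named transcripts still past the threshold. It was 4 without the 3 groups of widest spread between libraries, where 1 of the 14 stayed past, and 167 without the groups with raised ovule markers, where 8 did.

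Nectary, leaf, ovary and sepal of N. plumbaginifolia were compared to ask which transcripts mark the nectary, as values with no test of the authors' means. Cell wall invertase 4-like (XM_016593154.1) had 3056 to 10114 normalized counts over the 4 nectary stages, was listed at 0 in leaf, and had 473 (SD 223) in ovary and 22 (SD 2) in sepal. SWEET9 (XM_016615427.1) had 7619 (SD 232) at stage 12, was listed at 0 in leaf and sepal, and had 174 (SD 82) in ovary. Nectarin-1 (XM_016580669.1) had 1434 to 5425 in the nectaries, against 118 (SD 175) in leaf, 319 (SD 15) in ovary and 567 (SD 15) in sepal. TIFY 5A-like (XM_016617334.1), a jasmonate signalling repressor, had 95 to 294 in the nectaries and at most 4 elsewhere. The myb-related protein 305-like XM_016582512.1 had 949 to 5155 in the nectaries, was listed at 0 in leaf, and had 1343 (SD 311) in ovary and 1041 (SD 24) in sepal.

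Summed over all transcripts of the same Arabidopsis locus, the invertase had at least 3097 in the nectaries and at most 525 elsewhere, and the TIFY 5A locus at least 190 and at most 22. The nectarin-1 locus had at least 1932 and at most 1658. The SWEET9 locus had 154 at its lowest nectary stage, stage 6, below the 300 of the highest other tissue, and 7619 at stage 12. For many transcripts the sum over the locus did not differ as the single transcript did. By the rule of at least 4-fold between the lowest nectary stage and the highest other tissue, 1506 of 26808 transcripts were nectary-enriched (2341 without leaf, chosen after seeing the data) and 1926 depleted by the mirror rule (880 at pseudocount 10). By locus the counts were 83 and 262 of 11888. Of 1377 enriched transcripts with an Arabidopsis match, 90 (6.5%) lay in a locus enriched by the same rule, and of 1679 depleted ones 250 (14.9%). Whether reads of nectary and of the other tissues match the reference alike was not tested. The counts by transcript can therefore not be read as tissue differences alone. The Spearman correlation across transcripts of stage 12 with ovary was 0.52 and that of leaf with ovary 0.504, and by locus they were 0.864 and 0.76, which are correlations across genes and not across replicates.

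The transcripts of largest enrichment by the rule were a P322 defensin-like protein (XM_016594790.1, 3993 to 11680), the subtilisin-like protease SBT1.8 (XM_016577903.1, 3098 to 7390), an unannotated cDNA fragment (DQ460108.1, 2391 to 19681), a WW domain protein (XM_016653095.1, 2093 to 3715) and nucleolar GTP-binding protein 1-like (XM_016622504.1, 2020 to 2638). All 5 were listed at 0 in leaf, ovary and sepal, the defensin also in the nectaries of all other profiles, and of the 4 with a locus the defensin (5168 against 1952) and the WW domain protein (2150 against 1003) also had a lowest nectary sum above the highest other sum. The cDNA fragment's mean of 19681, at stage 9, had an SD of 11921, and its stage 9 mean of 10576 in N. benthamiana an SD of 16991. At stage 9 a poly(A) polymerase 4-like transcript (XM_016598866.1) had 7143395 (SD 4531179) in N. plumbaginifolia. D64052.1 had 293215 (SD 470803) at that stage in N. benthamiana. So 1 library can carry much of such means. Over the 4 stages of N. benthamiana, D64052.1 had 72247, 293215, 55023 and 134435, and the fragment 2429, 10576, 1519 and 3586. In N. plumbaginifolia the fragment had 2391, 19681, 2673 and 4536, and the polymerase-like transcript 493166, 7143395, 971980 and 982889. In both, the paired means rose and fell alike. In N. rustica and the joint profile, where the fragment had at most 44, its means and those of D64052.1 did not. The fragment is no clear nectary marker. Largest among the depleted ones was the translationally-controlled tumor protein (NM_001329593.1), a growth-related protein, listed at 0 in all 4 nectary stages, with 17378 (SD 1202) in leaf, 19808 (SD 1536) in ovary and 14713 (SD 1322) in sepal, and its locus sum was 0 in the nectaries as well. The nectaries of the other 4 profiles had 2962 to 30539 of it, so it is not absent from nectaries of the genus. Whether its 0 comes from how these nectary reads match the reference was not tested. The ketol-acid reductoisomerase XM_016648333.1 and the tubulin alpha chain NM_001325628.2 were listed at 0 in the nectaries too, but their loci held at least 3000 and 5344 counts there. An insect injury-induced proteinase inhibitor (DQ071272.1) was listed at 0 against 2812 to 13002. A cytochrome P450-like transcript (D64052.1) had 11 to 97 in the nectaries and 182609 to 235577 elsewhere, against 55023 to 1597532 in the nectaries of the other profiles. The poly(A) polymerase 4-like transcript went the other way, with 493166 to 7143395 in the nectaries and 253 to 744 elsewhere. Whether its reads and those of D64052.1 come from the genes described was not tested.

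As a list, photosynthesis was lower in the nectary than in the mean of the other tissues, with a median of -3.28 over 93 transcripts, below all 10000 random lists matched on level, and lower in 30 of 31 loci. The authors' deposited table calls 65 of the 93 lower at stage 12 than in leaf and 8 higher. The nectary and floral regulators had a median of 3.07 (above all random lists, 10 of 11 loci higher), in which the transcripts of auxin response factor 6 went both ways (XM_016580372.1 at 8.07 and XM_016580371.1 at -9.45) within 1 locus. The cell division list had a median of 1.12 (above all random lists, 33 of 37 loci higher), and the authors' deposited table calls 49 of its 81 transcripts higher than in sepal and 46 lower than in ovary at stage 12. Starch synthesis (-0.65, percentile 0.42, 12 of 16 loci lower), starch breakdown (-0.51, percentile 0.43, 17 of 19 loci lower) and vascular markers (-1.34, percentile 2.26, 8 of 8 loci lower) had negative medians. The ovule markers had a median of 1.87 over 8 transcripts (percentile 98.12, 3 of 4 loci higher), but at stage 12 the authors' deposited table calls 0 of the 8 higher and 4 lower than in ovary. The sucrose, nectarin, jasmonate, carotenoid, senescence, nicotine, pollen-named, style and trichome lists had medians from -0.42 to 1.30 and percentiles from 6.28 to 92.75.

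**Figure D5:**
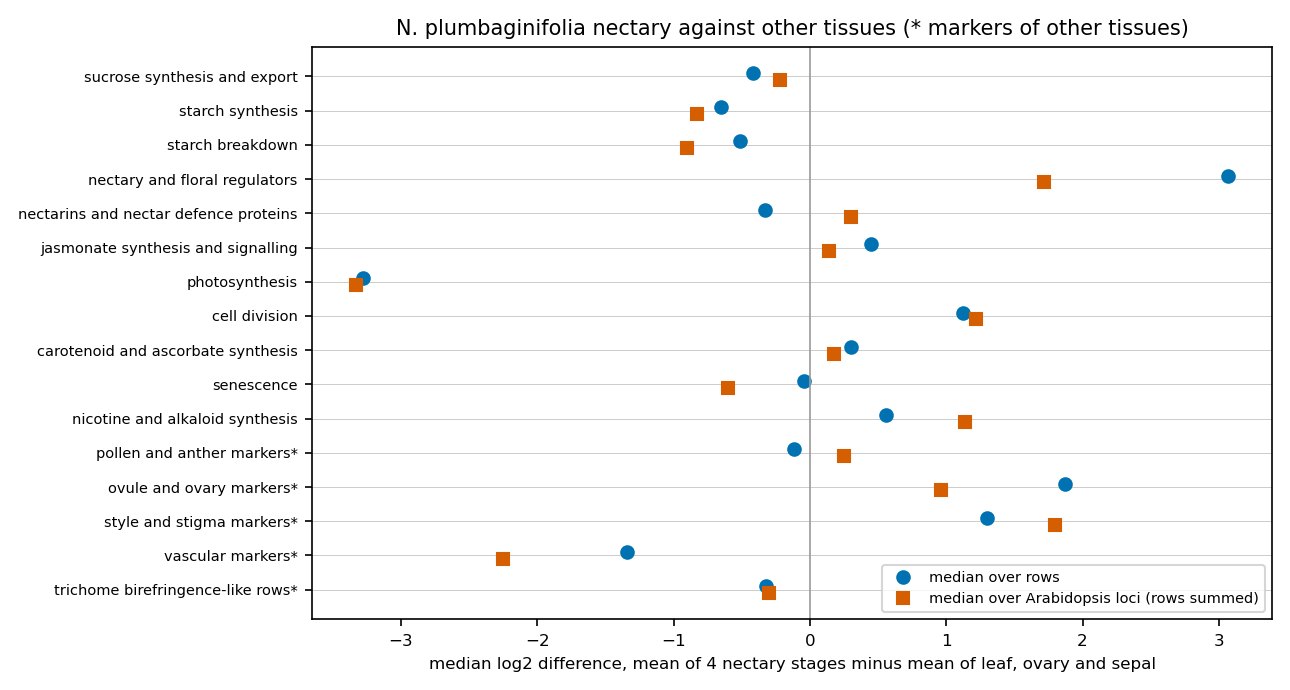
Median log2 difference between the mean of the 4 nectary stages and the mean of leaf, ovary and sepal in N. plumbaginifolia (x axis) for each gene list, over transcripts (circles) and over Arabidopsis loci with their transcripts summed (squares). Photosynthesis lies at -3.28 and -3.33 and the nectary and floral regulators at 3.07 and 1.72.

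At stage 12 the nectary differed by 2-fold or more from leaf in 14902 transcripts (55.6%), from ovary in 14306 (53.4%) and from sepal in 16098 (60.0%), and by locus in 34.9%, 27.6% and 37.9%. Unlike matching of reads between the tissues, which was not tested, may add to the shares by transcript. The authors' deposited table calls 8241 transcripts for leaf, 13139 for ovary and 15258 for sepal, with its threshold not stated. The smallest called difference was 2.46-fold for leaf, whose libraries vary most (median SD over mean of 0.3233), and 1.24-fold and 1.21-fold for ovary and sepal.

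Whether the species differ in their stage 12 against stage 6 change is described here with no test, since none was planned for a table without values per library. A test from the means and SDs was not made. Beta-carotene hydroxylase 2-like (XM_016611556.1), of xanthophyll synthesis, went from 54 (SD 13) to 63056 (SD 918) in N. rustica and from 499 (SD 20) to 401 (SD 54) in N. glauca. Nectarin-1 went from 937 (SD 11) to 4586 (SD 2466) in N. glauca and from 6526 (SD 170) to 4331 (SD 79) in the joint profile. Of 8908 transcripts measured in all 5 profiles, 72 were higher and 27 lower by 2-fold or more in all 5, where independent changes would give 0.0759 and 0.0175, and 432 went in opposite directions in at least a pair of profiles. The number of opposite ones that independent changes would give was not computed. The 432 alone therefore show no difference between species. Across transcripts, the log2 changes of pairs of profiles correlated with a Spearman coefficient of 0.276 to 0.51 (median 0.322), and transcripts are not independent replicates.

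The transcripts measured ran from 21751 in N. plumbaginifolia to 28989 in the joint profile, and percentages here are of those measured in each profile. Within each profile, the number changed 2-fold or more from stage 6 to stage 12 was 3645 (14.9%) in N. benthamiana and 5182 (22.8%) in N. rustica. It was 8101 (35.6%) in N. glauca, 3763 (17.3%) in N. plumbaginifolia and 5873 (20.3%) in the joint profile. The authors' deposited table calls 7506, 9380, 8285, 6828 and 10250 for the same step. After stage 12 the 2-fold counts were 5712, 5931, 7846, 1772 and 6162 in the same order (23.4%, 26.1%, 34.5%, 8.1% and 21.3%). The authors' deposited table has 10573, 4618, 7611, 4397 and 3515 calls there. Stage 12 of N. glauca and the post secretory groups of N. rustica and the joint profile had the widest spread between libraries among the nectary groups. Between stages 6 and 9 the 2-fold counts were 3134, 3538, 2898, 4391 and 4993 (12.8%, 15.6%, 12.7%, 20.2% and 17.2%). From stage 9 to stage 12 they were 3641, 3064, 4971, 3441 and 1953 (14.9%, 13.5%, 21.8%, 15.8% and 6.7%). In all 5 profiles at once, 43 transcripts were higher and 76 lower by 2-fold from stage 12 to post secretory, 29 and 9 from stage 6 to 9, and 10 and 0 from stage 9 to 12.

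Nectary profiles grouped by species. The median Spearman correlation across transcripts was 0.963 (SD 0.024, 30 pairs) between stages of the same species, 0.251 (SD 0.131, 40 pairs) between species at the same stage and 0.237 (SD 0.129, 120 pairs) between species at different stages. Over the 1000 transcripts of highest variance the medians between species were -0.176 at the same stage and -0.188 at different stages. These correlations were not repeated on sums per locus, which raised that of stage 12 with ovary in N. plumbaginifolia from 0.52 to 0.864. Transcripts at 0 made up 18.91% (stage 12, joint profile) to 38.14% (stage 6, N. plumbaginifolia) of a nectary group. Unlike matching of reads to the reference can therefore not be told apart from a difference between species.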

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

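In this part the tests of ovary RNA by locus, of a few abundant transcripts, of normalization and of depth, and the repeats leaving out each profile, were chosen after the results were seen, and the other 3 tests before. Chance sets about 1 in 20 groups apart by the measure used, and 17 of 239 results tested had 1 of the 5 profiles far from the rest, 2 of them medians of lists.

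From stage 6 to stage 12, N. benthamiana stood apart for the translocator GPT2-like (XM_016596315.1) with 5.52 against a median of 1.69 in the others, and N. plumbaginifolia for a lipoxygenase (XM_016655402.1, -5.08 against -0.29) and a pistil-specific extensin (XM_016587754.1, 5.52, others 0). The sucrose list's median stood apart in N. glauca, with 1.3 against 0.19. Between stages 6 and 9, N. plumbaginifolia stood apart for the jasmonate repressor KC246551.1 (-2.09) and the same extensin (4.34), and N. rustica for cyclin-A3-1 (XM_016628439.1, -3.2). Between stages 9 and 12 they were the sugar transporter N3-like (XM_016608510.1, 6.81 in N. benthamiana), N-methylputrescine oxidase (AB289457.1, 1.81 in N. rustica), an extensin (XM_016648304.1, 0.57 in N. plumbaginifolia) and nectarin-3-like (XM_016588226.1, -3.17 in N. glauca). After stage 12, N. glauca stood apart for the isoflavone reductase homolog (XM_016630531.1, 6.51), AGL19 (XM_016629598.1, -7.48) and the photosynthesis list's median (5.87 against 2.35). In the same step N. rustica stood apart for nicotinate-nucleotide pyrophosphorylase (XM_016652759.1, -2.45), N. plumbaginifolia for XM_016648304.1 (-1.7) and the joint profile for another extensin (XM_016659538.1, -1.23). Some of these follow from absence: AGL19 and XM_016648304.1 had means of 0 at all stages of the other 4 profiles, XM_016587754.1 means of at most 1 there, and XM_016659538.1 means of 0 in 3 profiles. Any change stands apart in such a case. The nectarin-3-like value is a fall from a mean of 8 to 0, and the transcript had 0 throughout N. benthamiana and N. plumbaginifolia.

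In 25 cases the means and SDs place all 3 libraries of 1 group above all 3 of the other in 1 profile, and below them in another profile. These opposite differences were not tested. The values are the gap in log2 change between the highest and lowest of such profiles. In stage 12 against stage 6 they were beta-carotene hydroxylase 2-like (10.48, lower in N. glauca), the cell wall invertase (1.65), the ADP-glucose pyrophosphorylase (2.84), myb-related protein 305-like (3.49), nectarin-1 (2.88) and nectarin 4 (3.63). In stage 9 against stage 6 they were the hydroxylase (5.05), the invertase (2.35), sucrose-phosphate synthase (0.59), beta-amylase 1-like (1.7), CRABS CLAW-like (1.1), myb-related protein 305-like (1.43), nectarin-1 (1.63) and nectarin 4 (2.2). In stage 12 against stage 9 they were a GPT2-like transcript (XM_016581980.1, 3.93), histone H2AX-like (XM_016624096.1, 4.19), ornithine decarboxylase (AF127242.1, 4.68), the pollen protein LAT52-like (XM_016580587.1, 8.15) and SWEET9 (3.52, lower in N. rustica). In that step they were also sucrose-phosphate synthase (1.53), CRABS CLAW-like (1.16), nectarin-1 (1.69) and nectarin-3-like (3.84). After stage 12 they were the ADP-glucose pyrophosphorylase (2.09) and nectarin 4 (4.66).

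Ovule identity genes were higher at stage 9 than at stage 6 in N. plumbaginifolia nectaries, with a median of 3.19 over 7 measured ovule markers. A few transcripts taking most of the counts would scale all others by 1 factor and move the other lists alike. Of the 15 other lists 1 (6.7%), style with 2.27, had a median of at least 0.5 times the ovule median, which argues against it. RNA of the ovary samples' makeup was tested on 49 loci specific to the ovary: 39 were higher at stage 9, but only 38.8% implied a share of ovary RNA within 3-fold of their median of 9.2% (quartiles 1.2% and 26.7%), which argues against ovary RNA in that makeup as the whole cause. Of single ovary-specific transcripts, the 148 measured in nectaries of N. plumbaginifolia had a median of 2.03 at stage 9 against stage 6 (0.05 to 0.18 in the other 4 profiles), which goes with ovary RNA. A low level at stage 6 was part of their choice, though, and the median over all 552 was 0. The share test on single transcripts gave 0.0% and decides nothing, since counts moved between transcripts of the same locus. RNA of a part of the ovary, such as ovules alone, may have entered and was not tested, and a rise within the nectary at this stage stays open as well.

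The falls after secretion were smaller in N. plumbaginifolia, with a median of -1.66 against -4.28 in the others over 47 transcripts chosen for a 4-fold fall in these. Such a choice favours a smaller fall in the profile left out of it, so it was repeated leaving out each other profile. The gap, 2.62 for N. plumbaginifolia, was then -1.08 to 1.13 over 13 transcripts each. A wrong factor in the authors' normalization would move falling and rising transcripts alike and leave the difference between their gaps as it was. That difference was 4.46 (95% of redrawn sets of transcripts between 3.64 and 5.77), with 15 transcripts that rose 4-fold in the others. It was -1.95 to 0.36 with each other profile left out, the highest upper bound being 3.38, and with 2-fold changes it was 2.61 against -2.56 to 0.80. This argues against such a factor as the whole cause. If stage 12 tissue were mixed in, falling transcripts would keep about the same share, and 93.6% kept a share within 3-fold of the median of 31.7% (53.8% to 76.9% with each other profile left out). Rising ones would keep most of their rise, but over the 15 the rise was 1.51 against 3.35. The ratio of 0.451 lies between the bounds set, and so does that of 0.373 with 2-fold changes. With each other profile left out these ratios were 0.63 to 1.973, over only 3 to 5 transcripts, and 0.808 to 2.366. Mixed stage 12 tissue therefore cannot be told apart from a species difference or an earlier collection, both untested.

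Among the nectary groups, libraries varied most in stage 12 of N. glauca, post secretory of N. rustica and post secretory of the joint profile, with a median SD over mean of 0.1554, 0.2011 and 0.2273. Variance over mean was at least 6.8 times higher at means of 1000 to 3000 than at 100 to 200, which argues against low depth as the whole cause. It also rose in groups of less spread, from 1.877 to 13.186 in post secretory N. glauca and from 1.829 to 13.579 in ovary. The measure therefore does not set the 3 groups apart, and low depth beside other variation stays open. Libraries of different stages in 1 group would vary most in transcripts that change with stage, and the correlation of spread with stage change was 0.226 or more in these groups and at most 0.181 in the others. That lies between the bounds set, so different stages in 1 group cannot be told apart from other variation between libraries. No biological explanation was tested.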

How the results depend on the processing

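Planned before the values were seen were the pseudocounts, minimums, rescaling, no variance trend, fold thresholds, matching of list members, the sign-flip count and leaving out each profile. Chosen after seeing the data were the tests with both copies of the joint profile, with sums per Arabidopsis locus, without leaf, without the 3 groups of widest spread and without the 7 groups with raised ovule markers. No paired analysis was possible because no values per library are given, so single libraries could not be paired, while the profile block of the test pairs the stage means of each profile. For the same reason other normalizations of counts, leaving out single libraries and a library block were not run. Depth is not known, so what it limits was not tested. The cause of the changes below was not tested, except that fewer groups or profiles leave fewer residual degrees of freedom and that sums per locus merge transcripts. Counting both copies enters identical values as separate profiles, which makes p too small. Its higher counts and kept calls are therefore no support.

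Of 29 named calls from stage 6 to 12 and stage 12 to post secretory, 0 reversed under any of these alternatives. Each of the 29 had the same direction in all profiles. Other pseudocounts, other minimums, no variance trend, leaving out a profile and counting both copies could therefore reverse none of them. For these alternatives the 0 says nothing about how stable the calls are. A reversal was possible only with rescaling or with groups left out. All 29 stayed past the threshold with rescaling, without the variance trend and with both copies counted, 28 at pseudocount 0.1 and with no minimum, 24 at pseudocount 10, and all 23 that could be fitted at a minimum mean of 100. Without a profile, 12 (N. benthamiana), 5 (N. rustica), 9 (N. glauca), 21 (N. plumbaginifolia) and 4 (joint profile) stayed. Without the widest-spread groups 9 stayed and without the raised-ovule groups 8. Over all named transcripts and lists, 2987 values kept direction and side, 175 lost and 82 gained a call, and 108 reversed.

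The count past the threshold from stage 6 to 12, 307, was 546 at a minimum mean of 100, 2275 with both copies counted, 1364 by locus, 72 without the widest-spread groups, 0 without the raised-ovule groups (limma; 4967 unadjusted), and 2602 moved one way in all profiles. After stage 12, 288 became 463, 1967, 1410, 4 and 167 in the same order, and 2325 moved one way. For stages 6 to 9, 0 by limma (2990 unadjusted) became 111 with both copies counted, and 2166 moved one way. For stages 9 to 12, 0 by limma (1776 unadjusted) became 2 at a minimum mean of 100, 3 with both copies and 2 by locus, and 1431 moved one way. Leaving out each profile gave 4 (N. rustica) to 114 (N. plumbaginifolia) from stage 6 to 12, 0 to 3 (N. glauca) from stage 6 to 9, and 2 (joint profile) to 724 (N. plumbaginifolia) from stage 12 to post secretory. Chance alone would move a share of 0.0625 of the transcripts one way in all profiles. The numbers that moved one way are therefore no counts of shared changes.

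At 4-fold in place of 2-fold, N. benthamiana had 907, 729, 813 and 1570 changed transcripts from stage 6 to 12, 6 to 9, 9 to 12 and 12 to post secretory. In that order N. rustica had 1304, 744, 829 and 1887, N. glauca 2435, 422, 1269 and 3122, N. plumbaginifolia 1087, 1122, 507 and 261, and the joint profile 1813, 1195, 293 and 1653. The transcripts measured ran from 21751 in N. plumbaginifolia to 28989 in the joint profile, so these counts do not rank the profiles. N. glauca from stage 6 to 9 had 1829 at pseudocount 10 and 4459 with no minimum. Transcripts changed one way in all profiles were 21, 6, 1 and 23 at 4-fold, and at pseudocount 10 they were 18 from stage 6 to 9 and 6 from stage 9 to 12. Nectary-depleted transcripts were 880 at pseudocount 10, and enriched ones 2341 without leaf. By locus 83 were enriched and 262 depleted, and 4150, 3283 and 4506 differed 2-fold from leaf, ovary and sepal. Between species the median correlations were -0.176 at the same and -0.188 at different stages over the 1000 transcripts of highest variance.

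Lists past camera's threshold from stage 6 to 12, 1, became 0 with an estimated correlation, 2 with both copies, 2 without the widest-spread groups and 2 without the raised-ovule groups, and 1 to 5 (without N. plumbaginifolia) without each profile. For stages 6 to 9, 3 became 0 with an estimated correlation, 0 with single-match members, 0 with the most abundant match, 1 at a minimum mean of 100, and 1 (without N. plumbaginifolia) to 5 (without N. benthamiana). Of these 3 lists, only cell division was run with single-match members. For stages 9 to 12, 3 became 0 with an estimated correlation, 1 with single-match members, 1 with the most abundant match, 7 rescaled, 5 with both copies, 7 without the widest-spread groups, and 3 to 6 (without N. rustica). Here too, only cell division of the 3 was run with single-match members. After stage 12, 6 became 1 with single-match members. Of the 6, the carotenoid, sucrose and vascular lists were not run there, and pollen and trichome lost their call. With an estimated correlation, sucrose and pollen lost theirs. Apart from the estimated correlation, the cell division call from stage 6 to 12 held under 15 of 16 alternatives. From stage 6 to 9, the cell division call held under 8 of 16, starch synthesis under 9 of 15 and ovule under 11 of 15. From stage 9 to 12, cell division held under 14 of 16, starch synthesis under 12 of 15 and vascular under 11 of 15. After stage 12, pollen held under 12 of 16, trichome under 15 of 16, photosynthesis under 16 of 16, carotenoid and sucrose each under 14 of 15 and vascular under 15 of 15. These tallies include the setting with both copies counted, whose kept calls are no support. The alternatives also refit the same means, so they are not independent checks.

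Camera's direction reversed for the lists named next, given with the median log2 change, whose sign can differ from camera's direction. Among lists past the threshold these are pollen after stage 12 with single-match members and cell division from stage 6 to 9 without N. rustica. With the most abundant match of each member: from stage 6 to 12, carotenoid -0.04 and starch synthesis 0.07, and from stage 6 to 9, carotenoid 0.28 and vascular 0.16. The same setting gave from stage 9 to 12, carotenoid -0.12 and nicotine -0.07, and from stage 12 to post secretory, jasmonate 0.24, nectarins 0.04, starch breakdown 0.04 and starch synthesis 0.04. Without the raised-ovule groups: from stage 6 to 12, carotenoid 0.09 and regulators 0.04, and from stage 6 to 9, regulators 0.18, nicotine 0.11, photosynthesis 0.07, pollen 0.05 and starch breakdown 0.12. The same setting gave from stage 9 to 12, carotenoid -0.04, nicotine -0.07, ovule 0.04 and sucrose 0.12, and from stage 12 to post secretory, cell division 0.21, jasmonate 0, ovule 0.24 and starch breakdown -0.14. Of the reversed values of lists only that of cell division after stage 12 (-0.22, short of the threshold) passed, at an adjusted p = 0.015. The same list passed as a fall without N. benthamiana (-0.51, adjusted p = 3e-05) and with both copies counted (-0.36, adjusted p = 0.011), so its direction depends on the groups used. With single-match members: from stage 6 to 12, trichome 0.02 and starch breakdown -0.01, and from stage 6 to 9, nectarins -0.12. The same setting gave from stage 12 to post secretory, nectarins -0.34, pollen -0.25 and starch breakdown -0.34. Without the widest-spread groups: from stage 6 to 9, trichome -0.03, and from stage 12 to post secretory, ovule 0.20 and starch breakdown -0.02. At a minimum mean of 100: from stage 6 to 9, vascular 0.20, and from stage 9 to 12, carotenoid 0.04, regulators 0, nicotine -0.11 and pollen 0.04. The same setting gave from stage 12 to post secretory, jasmonate -0.02, ovule 0.55 and starch synthesis 0. With both copies counted: from stage 6 to 9, vascular 0.01. At pseudocount 10: from stage 12 to post secretory, jasmonate -0.01. At pseudocount 0.1: from stage 12 to post secretory, starch breakdown 0. Rescaled by median of ratios: from stage 12 to post secretory, starch breakdown 0.03. Without each profile in turn the ranges from stage 6 to 12 were starch breakdown 0.02 to 0.22 and starch synthesis -0.04 to 0.21. From stage 6 to 9 they were carotenoid 0.03 to 0.37, cell division -0.42 to 0.09, trichome -0.03 to 0.06, pollen 0.04 to 0.11, sucrose -0.06 to 0.26 and vascular -0.07 to 0.14. From stage 9 to 12 they were carotenoid 0.04 to 0.09, regulators -0.11 to 0.07, nicotine 0 to 0.14 and photosynthesis 0.09 to 0.31. After stage 12 they were cell division -0.51 to -0.01, jasmonate -0.10 to 0.01, nicotine -0.30 to 0.05, ovule -0.31 to 0.13, starch breakdown -0.09 to 0.08 and starch synthesis -0.19 to 0.04.

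Named transcripts that reversed were all short of the threshold. Without the raised-ovule groups: from stage 6 to 12, CRABS CLAW-like 0.27 and myb-related protein 305-like 0.03, and from stage 6 to 9, ADP-glucose pyrophosphorylase 0.07 and CRABS CLAW-like 0.01. The same setting gave from stage 9 to 12, SWEET9 -0.47 and cell wall invertase -0.14, and from stage 12 to post secretory, pistil-specific extensin 0.39. With both copies counted: from stage 6 to 9, beta-amylase 1-like 0.13, and from stage 9 to 12, CRABS CLAW-like -0.11. The same setting gave from stage 12 to post secretory, ADP-glucose pyrophosphorylase -0.05. Without the widest-spread groups: from stage 9 to 12, cell wall invertase -0.07 and CRABS CLAW-like -0.40, and from stage 12 to post secretory, sugar transporter N3-like -0.20, ornithine decarboxylase -0.08, sucrose-phosphate synthase -0.09, ADP-glucose pyrophosphorylase -0.31 and nectarin 4 -0.34. Rescaled by median of ratios: from stage 9 to 12, CRABS CLAW-like -0.04. At pseudocount 10: from stage 9 to 12, nectarin-3-like 0.03, and from stage 12 to post secretory, ADP-glucose pyrophosphorylase 0. Ranges without each profile were, from stage 6 to 12, CRABS CLAW-like -0.31 to 0.15 and myb-related protein 305-like -0.53 to 0.34. Between stages 6 and 9 they were cell wall invertase -0.03 to 0.56, sucrose-phosphate synthase -0.02 to 0.19, beta-amylase 1-like -0.30 to 0.12 and CRABS CLAW-like -0.20 to 0.07. From stage 9 to 12 they were CRABS CLAW-like -0.18 to 0.17 and nectarin-3-like -0.70 to 0.26, and from stage 12 to post secretory pistil-specific extensin -0.31 to 0.01 and ADP-glucose pyrophosphorylase -0.36 to 0.16.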

Other observations

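The tests against other splits in this part were chosen after the results were seen, and the other values answer no question planned. Several transcripts made up much of single columns. A reference transcript described as nuclear poly(A) polymerase 4-like (XM_016598866.1) held 46.8% of the sum of N. plumbaginifolia stage 9 (7143395, SD 4531179, of 15248393). It held 5.8%, 10.9% and 11.5% at the other nectary stages of the species and 0.0% in all other groups. A cytochrome P450-like transcript (D64052.1) held 12.9% of stage 9 in the joint profile, with a mean of 1597532 and an SD of 2274468. Both SDs are wide, and shares per library cannot be read from the table, so 1 library can carry much of either share. In leaf, ovary and sepal of N. plumbaginifolia the polymerase-like transcript had only 253 to 744, and D64052.1 had 182609 to 235577. In the nectaries of that species D64052.1 had only 11 to 97. Whether the reads behind either transcript come from the gene described was not tested, so neither is read as expression of that enzyme. The phosphoenolpyruvate carboxykinase transcript XM_016579669.1, of an enzyme that makes sugar from organic acids, had authors' means of 128865, 192020, 117011 (SD 71612) and 4242 over the 4 stages of N. glauca.

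Some abundant stage 12 transcripts were at most 66 in all other profiles, and whether reads of different species match the reference alike was not tested. In N. benthamiana they were a secoisolariciresinol dehydrogenase-like transcript (XM_016585496.1, 162193, SD 5802), a metallothionein (XM_016634706.1, 28580), the nicotine demethylase relative CYP82E2 (DQ131887.2, 19485) and nitrate transporter 2.4 (XM_016653517.1, 10492). In N. rustica it was neoxanthin synthase (XM_016625496.1, 10114), of carotenoid synthesis, in N. glauca a reticuline oxidase-like transcript (XM_016623365.1, 20279, SD 12072), in N. plumbaginifolia a 6-domain proteinase inhibitor (DQ192596.1, 63706, SD 4011) and in the joint profile plastid-lipid-associated protein 3 (XM_016578205.1, 91263, SD 45112).

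Each count of transcripts past the threshold was set against 100 splits of its 10 group means, the real one included. From stage 6 to stage 12 only the real split gave as many (1 of 100; 307, highest other 1), and from stage 12 to post secretory 3 of 100 did (288, highest other 607). Most of these splits do not keep the pairing of stages within profiles that the test uses. Over the 16 swaps of the stages within profiles, which keep it, the real one alone gave 307 and 288 and the highest other was 0, but 1 of 16 is a share of 0.0625, so these are too few for a share under 0.05. The split with 607 sets the stage 12 means of N. benthamiana, N. rustica, N. glauca and N. plumbaginifolia and the post secretory mean of N. plumbaginifolia against the other 4 post secretory means and stage 12 of the joint profile. It keeps the real labels of N. benthamiana, N. rustica and N. glauca, and labels both means alike in N. plumbaginifolia and in the joint profile. It therefore still holds the real stage change of the former profiles and is no split free of it. Leaving N. plumbaginifolia out of the real comparison also gave more calls, 724. Why the split gave more than the real one was not tested further. For stage 9 against stage 6 and stage 12 against stage 9 limma placed 0 past the threshold (2990 and 1776 at an unadjusted p under 0.05), so 100 of 100 and 100 of 100 splits gave as many by construction (highest other 3 and 0), and the splits decide nothing.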
